A study of Homo sapiens with 24 samples.

How the data were processed

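RNA was measured in 24 libraries of human peripheral blood mononuclear cells: 2 treatments (DMSO or YKL-5-124), 2 times (6 and 24 h) and 2 arms told apart only by a letter in the sample titles, with 3 replicates in each of the 8 groups. Per the labels, cells were cultured in RPMI medium with fetal bovine serum, RNA was extracted after lysis, and libraries covered the 3' ends of transcripts (QuantSeq). According to the design text the study was normalized to cell number and the replicates are technical. The meaning of the letters M and P, the dose and the donors are not given in the sources used here.

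The values were used as deposited by the authors, in FPKM. The submitters' processing notes name HISAT2, Cuffnorm and hg19, without versions. The unit follows from Cuffnorm and from the values, which are not whole numbers. How the authors rescaled the values is not stated, but the design text speaks of normalization to cell number. The 92 ERCC spike-ins stood at nearly the same level in every library while gene totals differed, so the deposited scale was read as tied to spike-in RNA. Each of the 24 tables held 26343 entries, of which 92 were spike-ins and 26251 genes. No value was 0. Every library had its own floor value, which 4889 genes held in every library, so values near it carry no information on expression. Counts and read depth are unknown from these values, so no counting error or detection limit was computed. FPKM divides by transcript length, which 3' end libraries do not call for, so levels were compared within genes and not between them. Spike-in entries made up 10.8 to 30.7% of the summed values per library. Gene coordinates were not used here, because the reference used here is on another genome build than the deposited values. How strand was set in the counting is not stated, so antisense, pseudogene and close paralog names were treated as uncertain. Older gene symbols were matched to current names with the synonyms of the annotation, and 38 list entries without a match among the tested genes were not tested.

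Log2 fold changes were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), in a single linear model with a mean for each of the 8 groups and all 24 libraries, with variances moderated by empirical Bayes along a trend in mean level. Genes with at least 1 FPKM in at least 3 libraries were tested, 13701 in all. A gene was called at a Benjamini and Hochberg adjusted p below 0.05 in two-sided tests. The 14 comparisons were the drug effect in each arm and time (4), the arms compared within DMSO and within YKL-5-124 at each time (4), the difference of the drug effect between arms at each time (2) and between times in each arm (2), and 24 against 6 h in DMSO in each arm (2). The 4 drug comparisons share no libraries. Fold changes are given with the standard error of the moderated fit and group levels with the SD of 3 libraries. Totals and medians per library were compared with two-sided exact permutation tests of the difference of means, for which 3 against 3 libraries give no p below 0.1.

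The 25 gene lists were written before the data were examined. They cover E2F and DNA replication, mitosis, MYC and ribosome biogenesis, energy metabolism, immediate early, activation, inflammatory, interferon, p53, BCL2 family, transcription kinase, ribosomal protein and stress genes, and markers of 9 blood cell types. Some entries belong to more than 1 list. Each list was tested with camera at a preset correlation of 0.01 between genes, with camera at a correlation estimated from the data, and with fry, with adjusted p over the 25 lists. Camera compares a list with the other tested genes, so a list that fell less than the others can rank above them with a negative median. Fry tests a list against no change. For each list the number of called members is given from the adjustment over all tested genes and also after adjusting over the list alone.

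Genes named in the text followed a rule set before the data were examined. For the 4 drug comparisons and the arms in DMSO these were the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 5 FPKM in at least 1 of the 2 groups and no overlap between their libraries. From each list came the 2 called members with the smallest adjusted p. CDK7, MYC, E2F1, MCL1, HEXIM1, POLR2A and CDKN1A were always included. For the differences of drug effects the rule took the 3 highest and 3 lowest called genes under the same FPKM minimum. Symbols starting with LOC, LINC, MIR, SNOR or RNU, Y-linked genes and XIST were left out. Part of the genes picked are named, and a further gene is not reported here. Genes higher or lower in all 4 drug comparisons were counted after these results were seen.

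Alternatives set beforehand were a minimum absolute log2 fold change of 1, leaving out each library and fitting the groups of a comparison alone. Next were the estimated correlation, no variance trend, no filter (21349 genes) and a stricter filter at a mean of 5 FPKM (7910 genes). The rest were a pseudocount of 0.1, replicate number as block, centring each library on its median, rescaling by the median spike-in and quantile normalization. A count model did not apply to FPKM. Chosen after seeing the data were the first principal component of the 45 spike-ins with a mean of at least 20 FPKM as a covariate (52.5% of their variance), this component together with centring, and centring together with the estimated correlation.

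In simulations 100 of 13701 genes changed by 1 and 100 by 2 (log2). The fit recovered 44 to 54% of changes of 1 and 90 to 98% of 2 in the 6 drug and DMSO arm comparisons. For the drug effect between arms at 6 h the shares were 16 and 74%. False calls numbered 2 to 10 and 1. No level shift was simulated, so false calls under one are unknown. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.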

Results

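RNA was measured in human peripheral blood mononuclear cells, the lymphocytes, monocytes and related cells of blood, after culture with YKL-5-124 or with its vehicle DMSO for 6 or 24 h. YKL-5-124 binds CDK7 covalently; CDK7 is the kinase of the general transcription factor TFIIH, which phosphorylates RNA polymerase II, and of the complex that activates the cell cycle kinases. The series title concerns E2F and MYC programmes in multiple myeloma, and these libraries show how blood mononuclear cells respond to the same inhibitor. The 24 libraries form 8 groups of 3. A further code in the sample titles, M or P, splits every treatment and time into 2 arms, called arm M and arm P here because the labels do not say what the letters stand for. No dose is given in the sources used here. The replicates are technical according to the design text, so each p-value measures the spread between such libraries and not between donors.

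Values were FPKM on a scale read from the values as tied to spike-in RNA. The total over genes ranged from 492922 to 1802015 FPKM per library, and 10316 to 12452 genes per library reached 1 FPKM. Read depth is unknown from FPKM alone. Correlations of log2 values were 0.941 to 0.972 within groups and 0.825 to 0.971 between groups. Group values are given as mean ± SD FPKM (n = 3). In parentheses after a gene stand its log2 fold change ± standard error, its limma adjusted p and, in the drug comparisons, its log2 fold change after centring each library on its median. A gene was called at an adjusted p below 0.05 over 13701 genes.

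The mean total over genes was lower with YKL-5-124 than with DMSO in both arms and at both times. In arm M the total over genes was 811742 ± 133218 FPKM with DMSO and 535089 ± 46903 with the inhibitor at 6 h, and 1226350 ± 21388 and 594122 ± 59391 at 24 h. In arm P it was 1171811 ± 229014 and 896523 ± 111120 at 6 h, and 1606568 ± 262424 and 685509 ± 119743 at 24 h. The ratios of treated to vehicle totals were 0.66, 0.48, 0.77 and 0.43 in that order. The summed spike-in entries stayed at 210775 to 223320 FPKM in the 8 group means. The median log2 fold change over all genes tested was -0.53 in arm M and -0.28 in arm P at 6 h (-0.45 without DMSO replicate 1), and -0.65 and -0.76 at 24 h. A two-sided exact permutation test of library medians gave p = 0.1 in each of the 4 comparisons (n = 3 per group), the smallest p that 3 against 3 libraries allow. For the totals it gave p = 0.1, except in arm P at 6 h, where the totals overlapped (exact p = 0.2).

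With this shift most genes called for the drug were lower on the deposited scale. Centring moved the level by -0.63 in arm M and -0.42 in arm P at 6 h, and -0.81 and -0.89 at 24 h. Centred values set genes against the bulk, but low genes fall little on log2(FPKM + 1), so theirs can be positive after any fall. Of called genes, 98.2%, 96.3%, 91.7% and 98.1% were lower (arm M at 6 and 24 h, then arm P), against 41.7%, 36.2%, 37.9% and 41.2% after centring. After quantile normalization, which also removes the level, 1915 higher and 1827 lower genes were called in arm M at 6 h and 2737 higher and 2219 lower at 24 h. In arm P they were 1903 higher and 1922 lower at 6 h and 2381 higher and 2060 lower at 24 h.

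**Figure D1:**
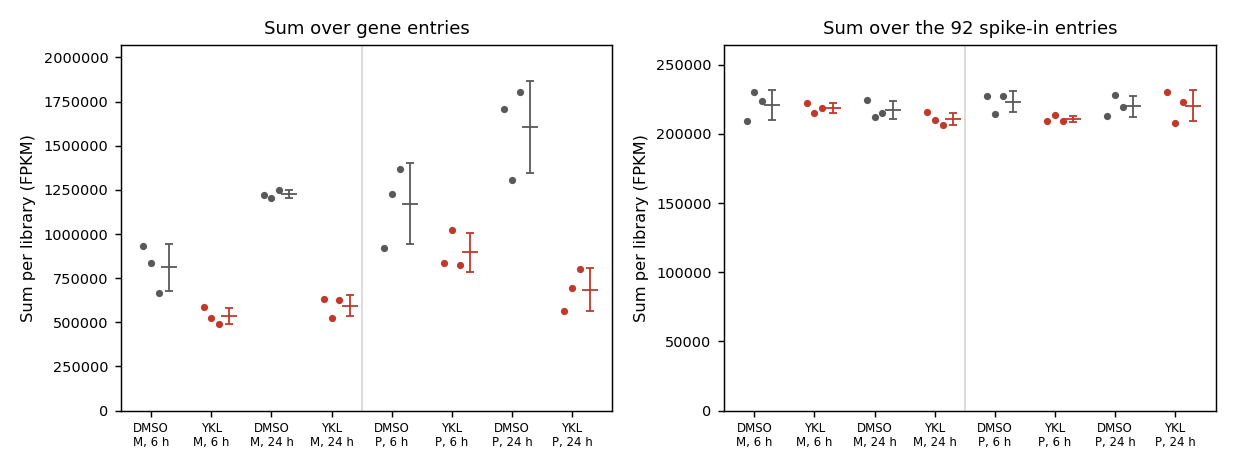
Sum of FPKM per library over genes on the left and over the 92 spike-in entries on the right, by treatment, arm and time; points are libraries (grey DMSO, red YKL-5-124), and the dash and bar beside them are the mean ± SD of 3 libraries. The gene total at 24 h was 594122 ± 59391 FPKM with YKL-5-124 against 1226350 ± 21388 with DMSO in arm M and 685509 ± 119743 against 1606568 ± 262424 in arm P.

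The arms differed widely before any drug effect. In DMSO, arm P held high levels of cytokine and lymphocyte activation transcripts that were low in arm M. IL2RA, a chain of the interleukin 2 receptor, stood at 333 ± 69 FPKM in arm P and 8.55 ± 2.7 FPKM in arm M at 6 h (5.14 ± 0.20, adjusted p = 6.1e-14), and at 414 ± 57 and 12.5 ± 1.4 FPKM at 24 h (4.94 ± 0.20, adjusted p = 1.1e-13). The type 2 cytokine gene IL4 rose by 5.72 and 5.26 on the log2 scale at the 2 times, the cytokine gene IL9 stood at 229.9 ± 49 FPKM against 0.222 ± 0.18 FPKM at 6 h, and CCL17, a chemokine that attracts T cells, at 478 ± 80.3 against 1.72 ± 0.68 FPKM. At 6 h, 25 of 25 T cell activation and cytokine genes rose (25 adjusted over the list alone, median 3.37, centred 3.22, camera adjusted p = 3.8e-23, adjusted p = 0.046 with an estimated correlation). At 24 h, 25 of 25 T cell activation and cytokine genes rose (25 adjusted over the list alone, median 2.72, centred 2.63, camera adjusted p = 1.4e-20, adjusted p = 0.076 with an estimated correlation).

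Proliferation and growth genes were higher in arm P as well. GINS2 and CDC45, parts of the replicative helicase, rose in arm P at 6 h, as GINS2 (4.67 ± 0.24, adjusted p = 7.5e-12) and CDC45 (3.45 ± 0.19, adjusted p = 9.7e-12). So did MYC (1.81 ± 0.24, adjusted p = 4.1e-06) and E2F1, which encodes a transcription factor of S phase genes (3.03 ± 0.21, adjusted p = 4.1e-10). At 6 h, 32 of 34 E2F and DNA replication genes rose (32 adjusted over the list alone, median 2.19, centred 2.04, camera adjusted p = 4.9e-19, adjusted p = 0.2 with an estimated correlation). At 24 h, 33 of 34 E2F and DNA replication genes rose (33 adjusted over the list alone, median 2.79, centred 2.71, camera adjusted p = 1.5e-24, adjusted p = 0.11 with an estimated correlation). Likewise, 29 of 29 MYC and ribosome biogenesis genes rose (29 adjusted over the list alone, median 2.19, centred 2.04, camera adjusted p = 1.3e-18, adjusted p = 0.2 with an estimated correlation) at 6 h. 28 of 29 MYC and ribosome biogenesis genes rose (29 adjusted over the list alone, median 2.12, centred 2.04, camera adjusted p = 2.7e-17, adjusted p = 0.16 with an estimated correlation) at 24 h. Further lists rose at 6 h, each with the count adjusted over the list alone first in parentheses. 17 of 25 G2 and mitosis genes (20, median 1.02, centred 0.86) and 15 of 16 glycolysis genes (15, median 1.45, centred 1.30) rose. 20 of 24 respiratory chain genes (21, median 1.34, centred 1.19) and 16 of 19 cholesterol synthesis genes (17, median 1.79, centred 1.64) rose. 9 of 12 heat shock genes (9, median 1.55, centred 1.39) and 13 of 16 ATF4 stress genes (13, median 1.44, centred 1.28) rose. 20 of 24 inflammatory NF-kB genes (22, median 1.81, centred 1.66) and 24 of 29 interferon response genes (24, median 1.14, centred 0.99) rose. 21 of 38 ribosomal protein genes (22, median 0.50, centred 0.35) rose. Camera called each of these 9 lists, with adjusted p up to 0.0019, but none with an estimated correlation (adjusted p 0.25 to 0.62). Over all 25 lists camera called 17 at 6 h and 18 at 24 h. With an estimated correlation it called 1 and 0 (4 and 6 at an unadjusted p under 0.05, 21 and 22 called by fry).

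Monocyte genes were lower in arm P. FCN1, which monocytes express for the lectin ficolin 1, fell from 246 ± 83 FPKM in arm M to 2.19 ± 1.6 FPKM in arm P at 6 h (-6.32 ± 0.33, adjusted p = 7.5e-12) and by 5.98 on the log2 scale at 24 h. The scavenger receptor gene CD36 fell as well, by 4.12 and 4.47. At 6 h, 12 of 20 monocyte markers fell and 2 rose (13 adjusted over the list alone, median -0.82, centred -0.97, camera adjusted p = 2.6e-06, adjusted p = 0.25 with an estimated correlation). At 24 h, 12 of 20 monocyte markers fell and 2 rose (14 adjusted over the list alone, median -1.40, centred -1.49, camera adjusted p = 1.5e-08, adjusted p = 0.19 with an estimated correlation). Other markers were lower at 6 h. 8 of 15 B cell markers (9, median -0.60, centred -0.75) and 6 of 15 NK and cytotoxic cell markers (6, median -0.41, centred -0.56) fell. 4 of 8 neutrophil markers (4, median -0.71, centred -0.86) fell. At 24 h, 3 of 3 erythroid markers (3, median -2.16, centred -2.25) and 5 of 8 neutrophil markers (6, median -0.76, centred -0.84) fell. 7 of 15 B cell markers (7, median -0.54, centred -0.63) fell. Camera called these marker lists, but none with an estimated correlation (adjusted p 0.11 to 0.6).

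In total, 3699 higher and 1664 lower genes were called between the arms in DMSO at 6 h and 3490 higher and 1928 lower at 24 h; after centring these counts were 3951 higher and 3368 lower at 6 h and 4086 higher and 3195 lower at 24 h. The median over all genes was 0.12 at both times. At 6 h it was 0.27 and -0.01 without arm M DMSO replicates 1 and 3, and 0.29, 0.03 and 0.05 without arm P DMSO replicates 1, 2 and 3; at 24 h it was 0.05, 0.26 and 0.03 without arm P DMSO replicates 1, 2 and 3. At 6 h, 5137 genes (37.5%) had no overlap between the libraries of the arms.

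Under YKL-5-124 the arms still differed in activation genes but little in replication genes by 24 h. At 24 h, 21 of 25 T cell activation and cytokine genes rose (21 adjusted over the list alone, median 2.64, centred 2.63, camera adjusted p = 6.7e-23, adjusted p = 0.042 with an estimated correlation). 29 of 29 MYC and ribosome biogenesis genes rose (29 adjusted over the list alone, median 1.55, centred 1.55, camera adjusted p = 6.4e-21, adjusted p = 0.15 with an estimated correlation). In contrast, 5 of 34 E2F and DNA replication genes rose (3 adjusted over the list alone, median 0.19, centred 0.18, camera adjusted p = 0.36, adjusted p = 0.93 with an estimated correlation). At 6 h 19 of 34 rose (19 higher adjusted over the list alone, median 0.76, centred 0.40). The monocyte list was lower in arm P. 17 of 20 monocyte markers fell (18 adjusted over the list alone, median -2.34, centred -2.34, camera adjusted p = 2.7e-21, adjusted p = 0.042 with an estimated correlation). At 6 h, 28 of 29 interferon response genes rose (29 adjusted over the list alone, median 2.32, centred 1.96, camera adjusted p = 4.7e-14, adjusted p = 0.26 with an estimated correlation). Calls numbered 4646 higher and 790 lower at 6 h and 2093 higher and 1176 lower at 24 h (3834 higher and 2989 lower, and 3010 higher and 2319 lower, after centring). Camera called 16 lists at 6 h and 15 at 24 h; with an estimated correlation it called 0 lists at 6 h, where 4 had an unadjusted p under 0.05 and fry called 20, and 2 at 24 h. The B cell list at 6 h had a median of -0.40 and a mean of 0.04, so its direction was mixed.

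The drug comparisons ask what the inhibitor changed within each arm and time. POLR2A, which encodes the largest subunit of RNA polymerase II, rose in all 4 drug comparisons, by 1.58 and 1.48 in arm M at 6 and 24 h, and 1.94 and 0.85 in arm P. At 24 h in arm M it stood at 76.8 ± 6.4 FPKM with the inhibitor and 27 ± 2.8 FPKM with DMSO. MYC, the growth regulator, fell in all 4, by 1.30 and 3.19 in arm M at 6 and 24 h, and 1.76 and 2.01 in arm P on the log2 scale; at 6 h in arm M its centred value was -0.67, which was not called, while the other 3 were. E2F1 fell in arm P (-2.26 and -3.82 at 6 and 24 h). In arm M it stood at 0.498 ± 0.071 and 0.992 ± 0.17 FPKM in DMSO at 6 and 24 h, with changes of -0.22 at 6 h (not called, centred 0.41) and -0.75 at 24 h (called, centred 0.07).

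CDK7 itself was called only in arm P at 24 h. Its log2 fold change was -0.31 and -0.21 in arm M at 6 and 24 h, and -0.58 and -0.89 in arm P, and after centring 0.32 and 0.61 in arm M at 6 and 24 h, and -0.16 and 0.01 in arm P, of which only the value in arm M at 24 h was called. HEXIM1, an inhibitor of the kinase P-TEFb, was not called in any of the 4 (0.08 and -0.07 in arm M at 6 and 24 h, and -0.01 and 0.21 in arm P), but it was called higher in each after centring (0.71 and 0.75 in arm M at 6 and 24 h, and 0.41 and 1.11 in arm P). MCL1, a survival gene of the BCL2 family, fell in arm M (-0.64 and -1.53) and in arm P at 24 h (-1.01), while in arm P at 6 h it was -0.38 (adjusted p = 0.09, called without DMSO replicate 1 at -0.53, adjusted p = 0.016). After centring it was -0.01 and -0.72 in arm M at 6 and 24 h, and 0.03 and -0.12 in arm P, and after quantile normalization 0.13 in arm M at 6 h and 0.30 in arm P at 24 h. CDKN1A, the cell cycle inhibitor p21, fell at 24 h (-1.68 in arm M and -2.51 in arm P). At 6 h it was -0.59 in arm M (not called, centred 0.04, called without DMSO replicate 2 at -0.84, adjusted p = 0.028). In arm P at 6 h it was -0.80 (adjusted p = 0.035, centred -0.38); that call ended at adjusted p = 0.16 without DMSO replicate 2, 0.16 without DMSO replicate 3, 0.12 without YKL-5-124 replicate 1 and 0.1 without YKL-5-124 replicate 3.

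**Figure D2:**
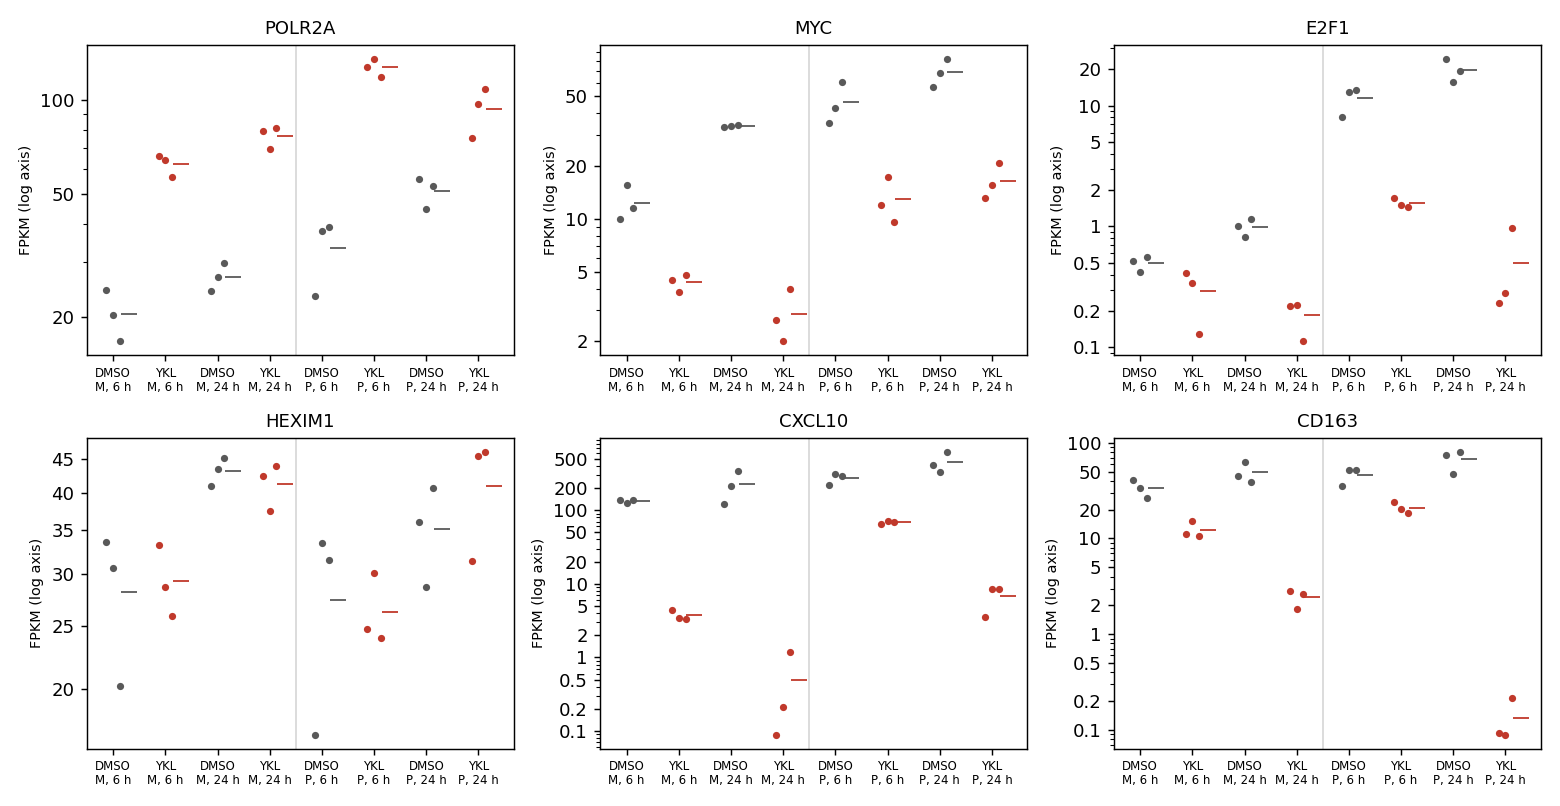
FPKM on a log axis of POLR2A, MYC, E2F1, HEXIM1, CXCL10 and CD163 by treatment, arm and time; points are libraries (grey DMSO, red YKL-5-124) and dashes are means of 3. POLR2A was higher with YKL-5-124 in all 4 comparisons (log2 fold change 1.58, 1.48, 1.94 and 0.85), MYC lower (-1.30, -3.19, -1.76 and -2.01), and HEXIM1 near its DMSO level (0.08, -0.07, -0.01 and 0.21, above 0 in each after centring).

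In arm M at 6 h, YKL-5-124 lowered interferon-induced genes, lineage markers of several blood cell types and heat shock genes most. CXCL10, an interferon-induced chemokine gene, fell from 133 ± 6.8 to 3.71 ± 0.57 FPKM (-4.84 ± 0.33, adjusted p = 6.4e-09, centred -4.21). In all, 24 of 29 interferon response genes fell (25 adjusted over the list alone, median -1.14, centred -0.51, camera adjusted p = 5.7e-07, adjusted p = 0.89 with an estimated correlation). GZMA, a granzyme of cytotoxic lymphocytes, fell (-1.99 ± 0.17, adjusted p = 8.5e-08, centred -1.36), as did EGR1, an immediate early transcription factor (-2.85 ± 0.25, adjusted p = 2.1e-07, centred -2.22). The small heat shock protein gene HSPB1 fell as well (-2.27 ± 0.22, centred -1.64).

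Camera called further lists lower in arm M at 6 h, and the first number in parentheses is the count adjusted over the list alone. 21 of 29 MYC and ribosome biogenesis genes (25, median -0.78, centred -0.15) and 18 of 24 respiratory chain genes (20, median -0.74, centred -0.11) fell. 10 of 12 heat shock genes (10, median -1.03, centred -0.40) and 15 of 21 T cell markers (18, median -0.81, centred -0.18) fell. 11 of 15 B cell markers (13, median -1.14, centred -0.51) and 12 of 15 NK and cytotoxic cell markers (14, median -0.97, centred -0.34) fell. 10 of 20 monocyte markers (10, median -0.74, centred -0.11) and 7 of 9 dendritic cell markers (8, median -1.19, centred -0.56) fell. Their camera adjusted p ran up to 0.018. Camera ranked the CDK7 complex and transcription kinase genes above the other genes (adjusted p = 0.018), although their median was -0.25 (0.38 after centring). Of 23 members 1 rose, POLR2A, and 3 fell (1 and 2 adjusted over the list alone), among them LARP7, a protein of the 7SK complex (-1.48 ± 0.23, centred -0.85). With an estimated correlation camera called none of the 25 lists (adjusted p = 0.89 for each of these 10; 0 lists at an unadjusted p under 0.05, and 22 called by fry).

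As a list, replication genes in arm M were not told apart from the bulk at 6 h. Only 10 of the 34 E2F members reached 5 FPKM in DMSO, and low genes can fall only a little on this scale. 16 of 34 E2F and DNA replication genes fell (16 adjusted over the list alone, median -0.58, centred 0.05, camera adjusted p = 0.75). PCNA, the replication clamp, fell (-1.45 ± 0.20, adjusted p = 3.7e-05, centred -0.82). For the lists that camera did not call, counts are given in the same form. 6 of 25 G2 and mitosis genes (1, median -0.35, centred 0.28) and 7 of 16 glycolysis genes (7, median -0.55, centred 0.08) fell. 12 of 23 immediate early genes (14, median -0.67, centred -0.04) and 12 of 25 T cell activation and cytokine genes (12, median -0.65, centred -0.02) fell. 11 of 24 inflammatory NF-kB genes (11, median -0.55, centred 0.08) and 11 of 22 p53 target genes (12, median -0.61, centred 0.02) fell. 7 of 15 BCL2 family genes (7, median -0.64, centred -0.01) and 15 of 38 ribosomal protein genes (15, median -0.51, centred 0.12) fell. 6 of 16 ATF4 stress genes (6, median -0.49, centred 0.14) and 12 of 19 cholesterol synthesis genes (12, median -0.68, centred -0.05) fell. 2 of 7 platelet markers (1, median -0.43, centred 0.20) and 0 of 3 erythroid markers (0, median 0.00, centred 0.63) fell. 5 of 8 neutrophil markers (5, median -0.80, centred -0.17) and 5 of 7 plasma cell markers (5, median -0.71, centred -0.08) fell. Among rises was the histone gene HIST1H2BD (2.11 ± 0.38, adjusted p = 0.00035, centred 2.74).

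In all, 101 higher and 5429 lower genes were called in arm M at 6 h, against 1878 higher and 1342 lower after centring, and 6489 genes (47.4%) had no overlap between treated and vehicle libraries, where chance gives 10%. The 5530 calls numbered 2629 without DMSO replicate 1 and 3236 without YKL-5-124 replicate 3.

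In arm M at 24 h interferon, monocyte and inflammatory genes fell most among the lists. CCL2, a chemokine gene that attracts monocytes, fell from 7617 ± 3689 to 65.5 ± 14 FPKM (-6.74 ± 0.43, adjusted p = 1.1e-10, centred -5.92). CCL8 and CXCL9, further chemokine genes, stood at 0.471 ± 0.22 and 0.273 ± 0.17 FPKM against 352 ± 248 and 84.1 ± 42 FPKM in DMSO. Here 29 of 29 interferon response genes fell (29 adjusted over the list alone, median -2.32, centred -1.50, camera adjusted p = 1.7e-17, adjusted p = 0.34 with an estimated correlation). Similarly, 23 of 24 inflammatory NF-kB genes fell (23 adjusted over the list alone, median -1.91, centred -1.10, camera adjusted p = 4.2e-09, adjusted p = 0.34 with an estimated correlation). Finally, 22 of 25 T cell activation and cytokine genes fell (23 adjusted over the list alone, median -1.45, centred -0.63, camera adjusted p = 6.4e-06, adjusted p = 0.35 with an estimated correlation), with the chemokine genes CCL4 (-4.31) and XCL2 (-3.69) among them.

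Markers of blood lineages fell with them at 24 h in arm M. The monocyte and macrophage receptor gene CD163 fell (-3.84 ± 0.24, adjusted p = 6e-11, centred -3.03) and MS4A7 (-4.06 ± 0.23, adjusted p = 2.3e-11, centred -3.24), while GZMA fell (-2.76 ± 0.17, adjusted p = 5.7e-11, centred -1.95) and the B cell antigen MS4A1 (-2.07 ± 0.20, adjusted p = 4e-08, centred -1.26). Of the marker lists, 17 of 20 monocyte markers fell (18 adjusted over the list alone, median -2.15, centred -1.34, camera adjusted p = 8e-07, adjusted p = 0.34 with an estimated correlation). Other marker lists fell, the first number in parentheses being the count adjusted over the list alone. 15 of 15 B cell markers (15, median -1.57, centred -0.76) and 7 of 7 plasma cell markers (7, median -1.78, centred -0.97) fell. 8 of 9 dendritic cell markers (8, median -1.73, centred -0.92) and 13 of 15 NK and cytotoxic cell markers (14, median -1.22, centred -0.41) fell. 18 of 21 T cell markers (18, median -1.06, centred -0.25) fell. Camera called these 5 lists (adjusted p up to 0.0024), and none with an estimated correlation (adjusted p 0.34 to 0.77).

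MYC and translation genes fell in arm M at 24 h. 26 of 29 MYC and ribosome biogenesis genes fell (26 adjusted over the list alone, median -1.04, centred -0.23, camera adjusted p = 0.0024, adjusted p = 0.78 with an estimated correlation). 34 of 38 ribosomal protein genes fell (34 adjusted over the list alone, median -0.96, centred -0.15, camera adjusted p = 0.00033, adjusted p = 0.78 with an estimated correlation). NME1, a nucleotide kinase gene under MYC control, fell (-2.11 ± 0.26, adjusted p = 1.1e-06, centred -1.30). Camera called further lists, with counts in the same form. 20 of 23 immediate early genes (22, median -1.10, centred -0.29) and 22 of 24 respiratory chain genes (22, median -0.86, centred -0.05) fell. 14 of 16 ATF4 stress genes (15, median -0.98, centred -0.17) fell. Their adjusted p was 0.55 to 0.78 with an estimated correlation. MTHFD2, of mitochondrial folate metabolism, fell (-2.61 ± 0.19, adjusted p = 8.3e-10, centred -1.80). Low levels limited most replication genes (11 of 34 E2F and 1 of 25 G2 genes reached 5 FPKM in DMSO). 13 of 34 E2F and DNA replication genes fell (10, median -0.48, centred 0.33, camera adjusted p = 0.35). 10 of 25 G2 and mitosis genes fell (10, median -0.36, centred 0.45, camera adjusted p = 0.36). The GTPase gene RHOB rose (2.08 ± 0.25, adjusted p = 8.9e-07, centred 2.89), from 4.1 ± 0.049 to 20.6 ± 1.4 FPKM. In all, 279 higher and 7287 lower genes were called, against 3627 higher and 2058 lower after centring, and 8926 genes (65.1%) had no overlap. With an estimated correlation none of the 25 lists was called by camera (2 at an unadjusted p under 0.05, 24 called by fry).

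In arm P at 6 h the inhibitor lowered replication and mitosis genes most among the lists. TYMS, thymidylate synthase, fell from 13.2 ± 4.3 to 0.601 ± 0.86 FPKM (-3.22 ± 0.31, adjusted p = 2.3e-07, centred -2.81), PCNA from 242 ± 49 to 31.6 ± 6.2 FPKM (-2.89 ± 0.20, adjusted p = 7.2e-09, centred -2.48), and CDT1, a licensing factor of replication origins (-2.94 ± 0.22, adjusted p = 1.2e-08, centred -2.52). CDK1, the mitotic kinase, fell (-2.55 ± 0.27, adjusted p = 9.9e-07, centred -2.13). Of the lists, 31 of 34 E2F and DNA replication genes fell (32 adjusted over the list alone, median -1.87, centred -1.45, camera adjusted p = 3.2e-26, adjusted p = 0.17 with an estimated correlation). 21 of 25 G2 and mitosis genes fell (23 adjusted over the list alone, median -1.14, centred -0.72, camera adjusted p = 1.9e-10, adjusted p = 0.27 with an estimated correlation).

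Cytokine genes fell in arm P at 6 h too. 16 of 25 T cell activation and cytokine genes fell (17 adjusted over the list alone, median -1.06, centred -0.64, camera adjusted p = 4.5e-06, adjusted p = 0.72 with an estimated correlation). CCL4 fell (-2.95 ± 0.28, adjusted p = 2.2e-07, centred -2.53), IL2, the T cell growth factor (-2.78 ± 0.36, adjusted p = 1.5e-05, centred -2.36), and the neutrophil chemokine gene CXCL2 (-3.31 ± 0.36, adjusted p = 1.3e-06, centred -2.89). The monocyte coreceptor gene CD14 fell (-2.51 ± 0.24, adjusted p = 2.2e-07, centred -2.10), and TCF7, a transcription factor of naive T cells (-2.04 ± 0.28, adjusted p = 2.9e-05, centred -1.63). Camera also called lists whose counts follow, the first number in parentheses being the count adjusted over the list alone. 10 of 12 heat shock genes (10, median -0.80, centred -0.39) and 11 of 16 ATF4 stress genes (12, median -0.82, centred -0.41) fell. 11 of 29 MYC and ribosome biogenesis genes (15, median -0.59, centred -0.18) and 12 of 24 inflammatory NF-kB genes (14, median -0.66, centred -0.25) fell. 11 of 21 T cell markers (13, median -0.73, centred -0.31) and 6 of 9 dendritic cell markers (6, median -0.93, centred -0.51) fell. Their adjusted p was 0.8 to 0.92 with an estimated correlation. Camera again ranked the CDK7 complex and transcription kinase list above other genes (adjusted p = 0.026, 0.97 with an estimated correlation), with a median of -0.01 (0.41 after centring) and 2 higher and 2 lower of 23 (2 and 2 adjusted over the list alone).

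Interferon genes did not fall as a list in arm P at 6 h. Of 29 members 6 fell and 1 rose (1 higher and 6 lower adjusted over the list alone, median -0.28, centred 0.14, camera adjusted p = 0.64). IFIT2, an interferon-induced antiviral gene, rose (1.45 ± 0.23, adjusted p = 0.0001, centred 1.87), while CXCL10 fell (-1.98 ± 0.33, adjusted p = 0.00018, centred -1.57). The noncoding RNA NRIR, a regulator of interferon responses, rose from 2.64 ± 0.77 to 29.9 ± 0.56 FPKM (3.11 ± 0.48, adjusted p = 9.4e-05, centred 3.52), and the actin gene ACTA2 rose (2.92 ± 0.59, adjusted p = 0.0012, centred 3.34). ADAMTSL4-AS1, an antisense RNA whose assignment is uncertain because the strand setting of the counting is not stated, rose (2.88 ± 0.37, centred 3.29). Few members of the metabolic lists passed. 3 of 16 glycolysis genes (3, median -0.33, centred 0.09) and 3 of 24 respiratory chain genes (2, median -0.26, centred 0.16) fell. 3 of 38 ribosomal protein genes (3, median -0.27, centred 0.14) fell.

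In arm P at 6 h 265 higher and 2926 lower genes were called, against 2759 higher and 1682 lower after centring. No overlap was seen for 4777 genes (34.9%). The 3191 calls numbered 1839 without DMSO replicate 2, 1716 without DMSO replicate 3 and 1990 without YKL-5-124 replicate 3. The lowest estimate belonged to the pseudogene H3F3AP4 (-5.57 ± 2.02, adjusted p = 0.0496), whose reads its parent gene can share; its call ended at adjusted p = 0.14 without DMSO replicate 2, 0.17 without DMSO replicate 3, 0.11 without YKL-5-124 replicate 1, 0.094 without YKL-5-124 replicate 2 and 0.11 without YKL-5-124 replicate 3. With an estimated correlation none of the 25 lists was called by camera (2 at an unadjusted p under 0.05, 12 called by fry).

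In arm P at 24 h nearly all measured replication genes were lower, together with cytokine, interferon and monocyte genes. GINS2 fell from 85.7 ± 11 to 1.13 ± 0.59 FPKM (-5.37 ± 0.24, adjusted p = 4.9e-13, centred -4.48) and E2F1 from 19.9 ± 4.3 to 0.495 ± 0.41 FPKM (-3.82 ± 0.21, adjusted p = 1e-11, centred -2.92). In total, 33 of 34 E2F and DNA replication genes fell (33 adjusted over the list alone, median -3.05, centred -2.15, camera adjusted p = 4.1e-21, adjusted p = 0.17 with an estimated correlation). Alongside, 24 of 25 G2 and mitosis genes fell (24 adjusted over the list alone, median -1.86, centred -0.97, camera adjusted p = 9.7e-09, adjusted p = 0.23 with an estimated correlation), among them TOP2A, a DNA topoisomerase gene (-3.15). GZMB, a granzyme, fell from 2258 ± 402 to 62 ± 13 FPKM (-5.17 ± 0.23, adjusted p = 3.9e-13, centred -4.28), and IL9 from 313 ± 109 to 1.25 ± 0.16 FPKM. Likewise, 21 of 25 T cell activation and cytokine genes fell and 1 rose (21 adjusted over the list alone, median -2.35, centred -1.45, camera adjusted p = 2.4e-06, adjusted p = 0.31 with an estimated correlation).

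Monocyte genes in arm P at 24 h fell to low levels: CD163 from 67.1 ± 18 to 0.131 ± 0.071 FPKM (-5.88 ± 0.24, adjusted p = 7.8e-14, centred -4.98), and CCL8 from 2388 ± 616 to 4.5 ± 1.7 FPKM (-8.78 ± 0.54, adjusted p = 4.8e-11, centred -7.88). Of the lists, 20 of 20 monocyte markers fell (20 adjusted over the list alone, median -2.92, centred -2.02, camera adjusted p = 3.2e-12, adjusted p = 0.17 with an estimated correlation). Also, 29 of 29 interferon response genes fell (29 adjusted over the list alone, median -2.32, centred -1.43, camera adjusted p = 9.3e-12, adjusted p = 0.31 with an estimated correlation); the interferon-induced chemokine gene CXCL9 fell (-4.83 ± 0.32, adjusted p = 1.4e-10, centred -3.93). Growth and energy genes fell as well. 29 of 29 MYC and ribosome biogenesis genes fell (29 adjusted over the list alone, median -1.58, centred -0.69, camera adjusted p = 4.1e-06, adjusted p = 0.46 with an estimated correlation). 16 of 16 glycolysis genes fell (16 adjusted over the list alone, median -1.68, centred -0.78, camera adjusted p = 3.7e-05, adjusted p = 0.44 with an estimated correlation). 24 of 24 respiratory chain genes fell (24 adjusted over the list alone, median -1.25, centred -0.36, camera adjusted p = 0.0003, adjusted p = 0.47 with an estimated correlation). 38 of 38 ribosomal protein genes fell (38 adjusted over the list alone, median -1.50, centred -0.60, camera adjusted p = 5.4e-09, adjusted p = 0.44 with an estimated correlation). GAPDH, the glycolytic enzyme, fell (-2.63 ± 0.18, adjusted p = 3e-10, centred -1.73) and NCL, nucleolin of ribosome assembly (-2.18 ± 0.20, adjusted p = 1.5e-08, centred -1.29).

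Camera called further lists lower in arm P at 24 h, the first number in parentheses being the count adjusted over the list alone. 20 of 24 inflammatory NF-kB genes (20, median -1.56, centred -0.67) and 12 of 12 heat shock genes (12, median -1.35, centred -0.46) fell. 14 of 16 ATF4 stress genes (14, median -1.34, centred -0.44) and 20 of 21 T cell markers (20, median -1.19, centred -0.30) fell. 13 of 15 B cell markers (13, median -1.49, centred -0.59) and 9 of 9 dendritic cell markers (9, median -1.46, centred -0.57) fell. 6 of 7 plasma cell markers (6, median -1.75, centred -0.86) fell. For these lists the adjusted p was 0.23 to 0.52 with an estimated correlation. Lists that camera did not call follow in the same form. 14 of 23 immediate early genes (14, median -0.86, centred 0.04) and 11 of 22 p53 target genes (11, median -0.60, centred 0.30) fell. 9 of 15 BCL2 family genes (9, median -0.76, centred 0.13) and 13 of 23 CDK7 complex and transcription kinase genes (13, median -0.66, centred 0.23) fell. 13 of 19 cholesterol synthesis genes (14, median -0.75, centred 0.14) and 9 of 15 NK and cytotoxic cell markers (9, median -1.63, centred -0.73) fell. 1 of 8 neutrophil markers (1, median -0.19, centred 0.71) fell. Of 7 platelet markers 2 rose and 3 fell (2 higher and 3 lower adjusted over the list alone, median -0.08, centred 0.81), with PF4 rising from 12.1 ± 5.3 to 36.2 ± 9.1 FPKM (1.58 ± 0.32, adjusted p = 0.00028, centred 2.47). The erythroid list was the only 1 of the 25 called by camera with an estimated correlation, and centring ended that call (adjusted p = 0.079). 2 of 3 erythroid markers rose (2 adjusted over the list alone, median 1.03, centred 1.92, camera adjusted p = 0.00012, adjusted p = 0.02 with an estimated correlation). Its risen members, the globin genes HBA2 (1.42) and HBB (1.03), stood at 6.77 ± 0.99 and 7.48 ± 3.2 FPKM, and HBA2 shares reads with HBA1. Without DMSO replicate 2 the call of HBA2 ended (adjusted p = 0.06), and that of HBB ended at adjusted p = 0.15 without DMSO replicate 2, 0.1 without YKL-5-124 replicate 2 and 0.067 without YKL-5-124 replicate 3.

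Among rises in arm P at 24 h, PID1, an adaptor protein gene, went from 0.291 ± 0.11 to 12.2 ± 1.8 FPKM (3.35 ± 0.23, adjusted p = 2.7e-10, centred 4.25), and ATP6V1C2, a proton pump subunit gene, rose (2.48 ± 0.32, adjusted p = 1.5e-06, centred 3.37). In all, 161 higher and 8139 lower genes were called, against 3989 higher and 2795 lower after centring, and 8291 genes (60.5%) had no overlap.

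**Figure D3:**
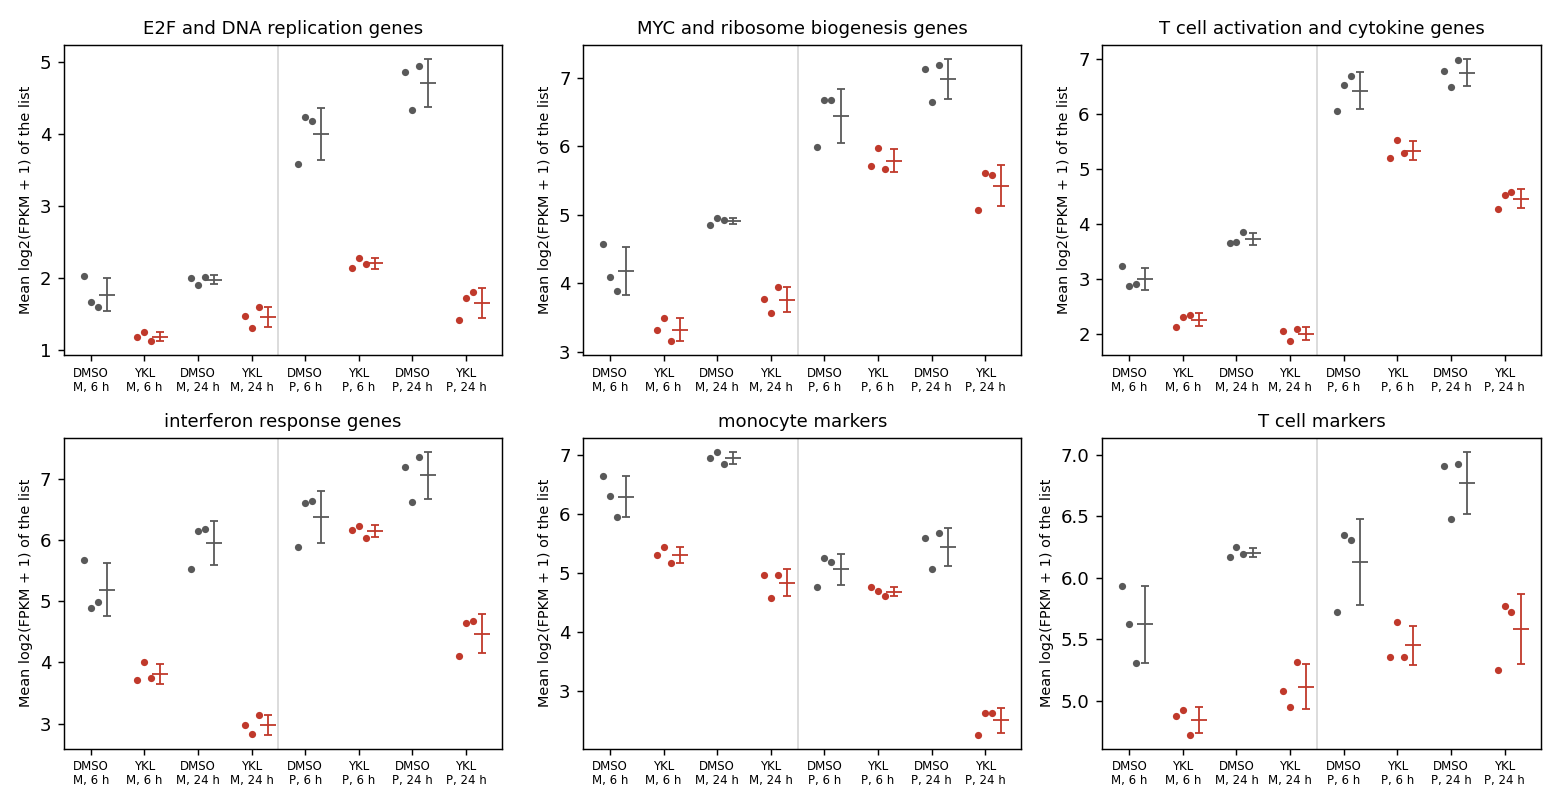
Mean log2(FPKM + 1) over the members of 6 gene lists in each library, by treatment, arm and time; points are libraries (grey DMSO, red YKL-5-124), and the dash and bar beside them are the mean ± SD of 3 libraries. At 24 h the E2F and DNA replication list stood at 4.71 ± 0.33 with DMSO and 1.65 ± 0.21 with YKL-5-124 in arm P. In arm M it was 1.97 ± 0.06 and 1.45 ± 0.14, where 11 of 34 members reached 5 FPKM in DMSO.

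**Figure D4:**
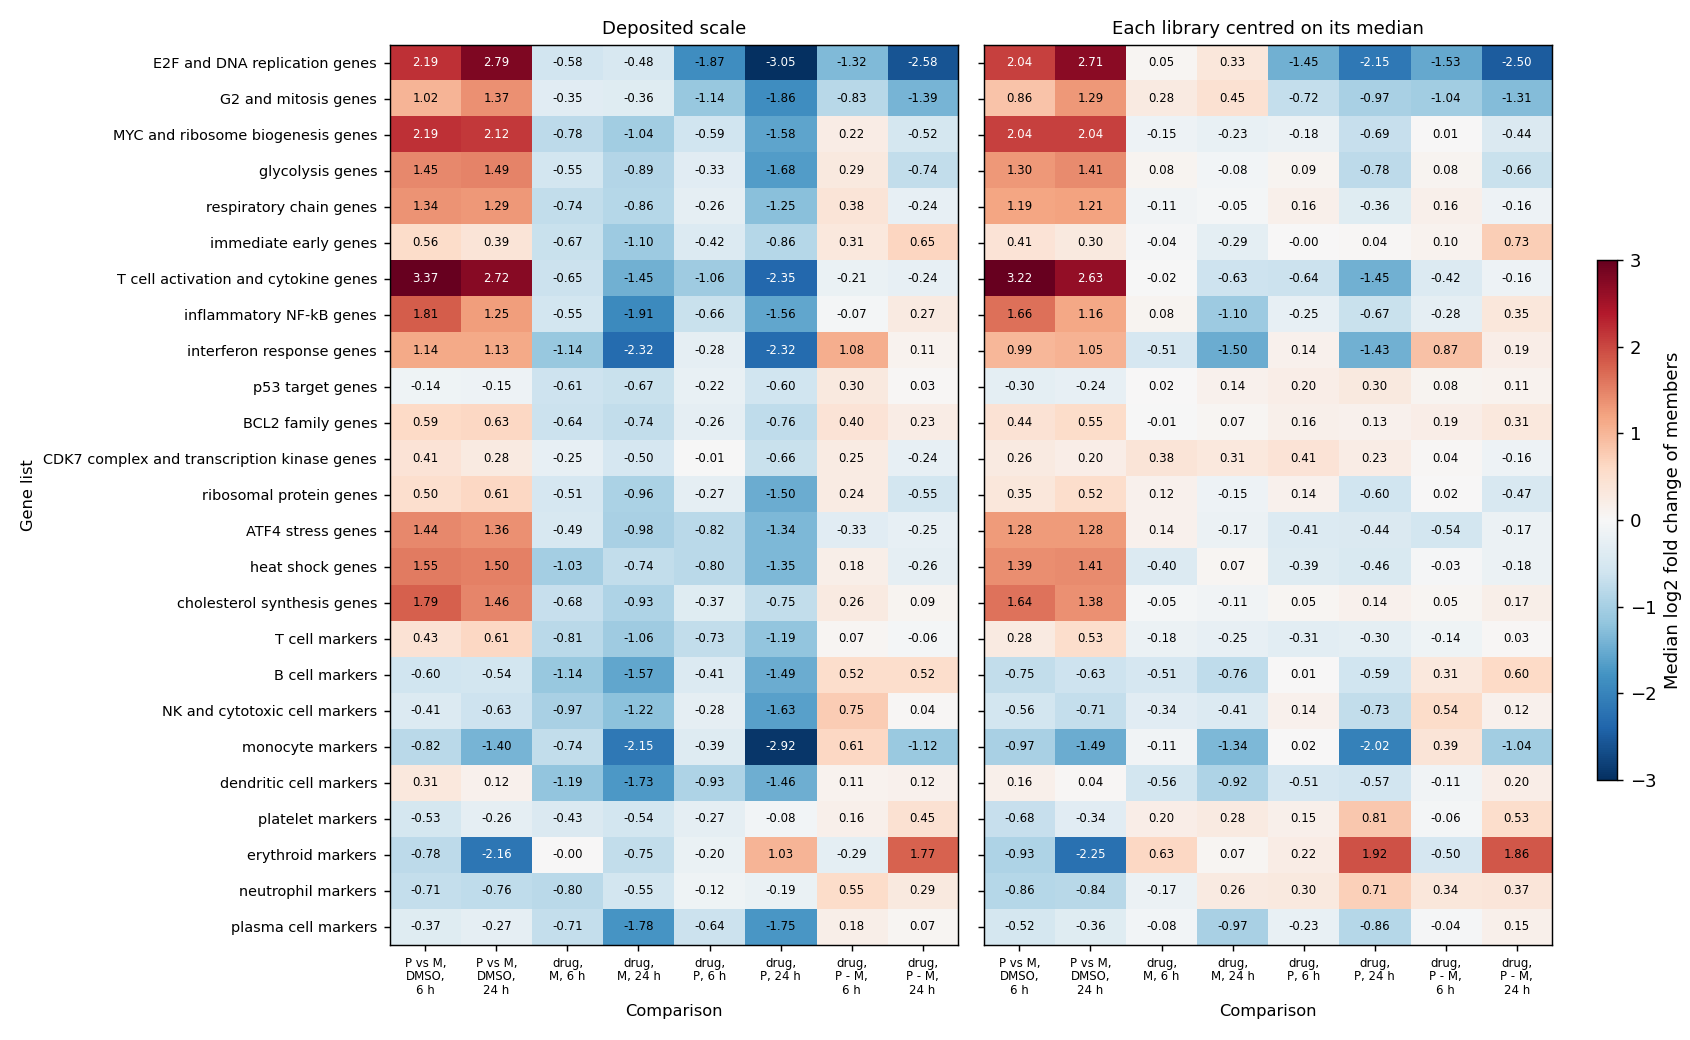
Median log2 fold change of the members of 25 gene lists (vertical axis) in 8 comparisons (horizontal axis), on the deposited scale (left) and with each library centred on its median (right); each cell prints its value and colour follows it. Drug medians were mostly below 0 on the left, while on the right many turned positive, and the E2F and DNA replication list in arm P stayed below 0 (-1.45 and -2.15 after centring).

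Many genes fell in several comparisons. At 24 h 5940 genes were called lower in both arms (1244 after centring), and at 6 h 46 higher (1064). Independent calls would give 4329, 420, 2 and 378 in that order. Calls depend on expression level, so this excess does not by itself show a shared response. Across all 4 drug comparisons 1941 genes were lower and 9 were higher on the deposited scale. After centring 350 were lower and 625 higher, where genes near the floor can add to the rises. The 9, which were also higher in all 4 after centring, were POLR2A, RHOB, HIST1H2BD, NR4A2, TSC22D3, TG, CCDC17, CFAP70 and SNAI3-AS1; they were named after their values were seen.

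The difference between the drug effects of the arms was tested directly. At 6 h TYMS and the PCNA-associated factor KIAA0101 fell more in arm P, as TYMS (-3.19 ± 0.43, adjusted p = 0.00043) and KIAA0101 (-2.91 ± 0.36, adjusted p = 0.00016); in arm M DMSO they stood at only 0.112 ± 0.022 and 1.38 ± 0.41 FPKM, which left little room to fall. Further, CXCL3, a neutrophil chemokine gene, fell more in arm P (-2.70 ± 0.52, adjusted p = 0.0081); the call of CXCL3 ended at a pseudocount of 0.1 (-2.67, adjusted p = 0.053). CXCL10 and EGR1 fell more in arm M, giving CXCL10 (2.85 ± 0.46, adjusted p = 0.0023) and EGR1 (2.72 ± 0.36, adjusted p = 0.00037). Here the lists rose or fell in arm P relative to arm M. At 6 h 15 of 34 E2F and DNA replication genes fell (22 adjusted over the list alone, median -1.32, centred -1.53, camera adjusted p = 3.5e-46, adjusted p = 0.016 with an estimated correlation). 3 of 25 G2 and mitosis genes fell (13 adjusted over the list alone, median -0.83, centred -1.04, camera adjusted p = 6e-24, adjusted p = 0.016 with an estimated correlation). At 24 h 31 of 34 E2F and DNA replication genes fell (33 adjusted over the list alone, median -2.58, centred -2.50, camera adjusted p = 1.5e-51, adjusted p = 0.012 with an estimated correlation). 17 of 25 G2 and mitosis genes fell (21 adjusted over the list alone, median -1.39, centred -1.31, camera adjusted p = 6.9e-20, adjusted p = 0.023 with an estimated correlation). Low levels in arm M limited both lists. Of members with at least 5 FPKM in arm M DMSO, a test chosen after the results were seen, the E2F list had 10 (median -0.69, centred -0.90, 1 called lower) at 6 h and 11 (median -1.95, centred -1.87, 10 called lower) at 24 h. The G2 and mitosis list had only 1 at each time, not called, so its difference cannot be separated from that of the arms in DMSO. For interferon genes at 6 h the difference had the other sign. 4 of 29 interferon response genes rose (19 adjusted over the list alone, median 1.08, centred 0.87, camera adjusted p = 1e-12, adjusted p = 0.61 with an estimated correlation).

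At 24 h the differences of IL9 and the metallothionein gene MT1A, namely IL9 (-7.02 ± 0.32, adjusted p = 4.5e-12) and MT1A (-5.54 ± 0.62, adjusted p = 4e-06), restated those of the arms in DMSO, since in arm M DMSO these genes stood at 0.113 ± 0.0091 and 0.506 ± 0.69 FPKM and could hardly fall. CD300E, a receptor gene of myeloid cells, was next (-5.01 ± 0.41, adjusted p = 5e-08). UBD, an interferon-induced ubiquitin-like gene, and DEFA4, a defensin gene of neutrophil granules, had the highest differences, as UBD (3.79 ± 0.45, adjusted p = 6.8e-06) and DEFA4 (4.17 ± 0.42, adjusted p = 1e-06); in arm P DMSO DEFA4 stood at 0.129 ± 0.022 FPKM and could not fall as in arm M. The erythroid list mean of log2 values went from 3.04 in DMSO to 2.29 in arm M and from 1.22 to 2.24 in arm P. For this difference 1 of 3 erythroid markers rose (3 adjusted over the list alone, median 1.77, centred 1.86, camera adjusted p = 0.00092, adjusted p = 0.023 with an estimated correlation). The NF-kB list at 24 h had a median of 0.27 and a mean of -0.01. Camera called 9 lists at 6 h and 10 at 24 h, of which 2 and 3 were called with an estimated correlation, namely the E2F and the G2 and mitosis list at both times and the erythroid list at 24 h, whose call centring ended (adjusted p = 0.065). At 6 h 93 higher and 68 lower genes were called (441 higher and 386 lower after centring) and at 24 h 302 higher and 457 lower (974 higher and 1238 lower after centring). The 161 calls at 6 h numbered 277 without arm M DMSO replicate 3, 93 without arm M YKL-5-124 replicate 3, 104 without arm P YKL-5-124 replicate 1 and 102 without arm P YKL-5-124 replicate 2.

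The drug effect also differed between 24 and 6 h within each arm. In arm M the chemokine genes CCL8 and CCL2 fell more at 24 h, as CCL8 (-5.55 ± 0.77, adjusted p = 0.00012) and CCL2 (-5.10 ± 0.61, adjusted p = 2.5e-05), as did the metallothionein gene MT1M (-5.51 ± 0.80, adjusted p = 0.00022). For the lists, 12 of 29 interferon response genes fell (24 adjusted over the list alone, median -1.25, centred -1.06, camera adjusted p = 4.6e-26, adjusted p = 0.16 with an estimated correlation). 14 of 24 inflammatory NF-kB genes fell (20 adjusted over the list alone, median -1.55, centred -1.36, camera adjusted p = 7.7e-23, adjusted p = 0.16 with an estimated correlation). In arm P CCL7, CCL8 and CCL13, which attract monocytes, fell more at 24 h, as CCL7 (-7.35 ± 1.31, adjusted p = 0.00071), CCL8 (-6.59 ± 0.77, adjusted p = 5.1e-06) and CCL13 (-6.51 ± 0.84, adjusted p = 2e-05), while PID1 and ATP6V1C2 rose more, as PID1 (2.74 ± 0.33, adjusted p = 7.9e-06) and ATP6V1C2 (2.32 ± 0.45, adjusted p = 0.0015). Here 17 of 20 monocyte markers fell (18 adjusted over the list alone, median -2.40, centred -1.93, camera adjusted p = 1.7e-21, adjusted p = 0.04 with an estimated correlation). 27 of 29 interferon response genes fell (29 adjusted over the list alone, median -2.44, centred -1.96, camera adjusted p = 3.3e-22, adjusted p = 0.17 with an estimated correlation).

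In arm M 16 higher and 335 lower genes were called for this difference (288 higher and 528 lower after centring), and camera called 10 lists, none with an estimated correlation (5 at an unadjusted p under 0.05, 9 called by fry). In arm P 66 higher and 2028 lower genes were called (807 higher and 1521 lower after centring), and camera called 14 lists, 2 of them with an estimated correlation, the monocyte list and the erythroid list (median 1.23, 1.71 after centring, adjusted p = 0.022, 0.074 after centring, which ended the call). The 2094 calls in arm P numbered 974 without 6 h DMSO replicate 1, 1074 without 6 h YKL-5-124 replicate 2, 1051 without 24 h DMSO replicate 1, 3583 without 24 h DMSO replicate 2, 1021 without 24 h DMSO replicate 3 and 950 without 24 h YKL-5-124 replicate 1.

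In DMSO the totals were higher at 24 h than at 6 h, with ratios of totals of 1.51 in arm M and 1.37 in arm P and centring shifts of 0.56 and 0.49. Genes rose with this level. 15 of 24 inflammatory NF-kB genes rose (23 adjusted over the list alone, median 0.97, centred 0.41, camera adjusted p = 2.4e-07, adjusted p = 0.73 with an estimated correlation) in arm M. 15 of 29 MYC and ribosome biogenesis genes rose (20 adjusted over the list alone, median 0.69, centred 0.13, camera adjusted p = 0.002, adjusted p = 0.73 with an estimated correlation). The ribosomal protein list in arm M changed sign with centring (0.39, -0.16 after centring), and so did the E2F list (0.20, -0.35 after centring). In arm P, 2 of 34 E2F and DNA replication genes rose (31 adjusted over the list alone, median 0.73, centred 0.24, camera adjusted p = 4.6e-06, adjusted p = 0.9 with an estimated correlation). Calls were 3240 higher and 17 lower in arm M (58 higher and 198 lower after centring) and 245 higher and 4 lower in arm P (7 higher and 19 lower after centring). Single libraries decided both counts. The 3257 calls in arm M numbered 6715 without 6 h DMSO replicate 1, 606 without 6 h DMSO replicate 2, 43 without 6 h DMSO replicate 3, 986 without 24 h DMSO replicate 1, 87 without 24 h DMSO replicate 2 and 57 without 24 h DMSO replicate 3. The 249 calls in arm P numbered 4 without 6 h DMSO replicate 1, 1196 without 6 h DMSO replicate 2, 1234 without 6 h DMSO replicate 3, 0 without 24 h DMSO replicate 1, 4673 without 24 h DMSO replicate 2 and 0 without 24 h DMSO replicate 3; the limma fits with 0 calls had 2521 and 2440 genes at an unadjusted p under 0.05. Of the 14 lists called by camera in arm M and 11 in arm P, none was called with an estimated correlation (1 list in each arm at an unadjusted p under 0.05, 20 and 14 called by fry).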

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

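The results listed here differed between arms or times by a test of the difference itself. The tests of explanations for the 3 patterns and with main effects removed were chosen after the results were seen.

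The drug effect differed between arm P and arm M for 161 genes at 6 h and 759 at 24 h, and between 24 and 6 h for 351 genes in arm M and 2094 in arm P. The 161 calls numbered 277 without arm M DMSO replicate 3, 93 without arm M YKL-5-124 replicate 3, 104 without arm P YKL-5-124 replicate 1 and 102 without arm P YKL-5-124 replicate 2. The 2094 calls numbered 974 without 6 h DMSO replicate 1, 1074 without 6 h YKL-5-124 replicate 2, 1051 without 24 h DMSO replicate 1, 3583 without 24 h DMSO replicate 2, 1021 without 24 h DMSO replicate 3 and 950 without 24 h YKL-5-124 replicate 1. Of the genes named for the drug, the difference between arms was called for 22 of 104 at 6 h and 37 of 101 at 24 h, and the difference between times for 24 of 96 in arm M and 62 of 103 in arm P.

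Between arms at 6 h the called genes at the ends were TYMS (-3.19), KIAA0101 (-2.91) and CXCL3 (-2.70) below, and CXCL10 (2.85), NRIR (2.83) and EGR1 (2.72) above. At 24 h they were IL9 (-7.02), MT1A (-5.54) and CD300E (-5.01) below, and DEFA4 (4.17) and UBD (3.79) above; IL9, MT1A and, at 6 h, TYMS were near the floor in arm M DMSO, and DEFA4 in arm P DMSO, so these differences restate those of the arms in DMSO. The call of NRIR ended without each of 10 of the 12 libraries (adjusted p 0.053 to 0.13), all but arm M DMSO replicate 3 and arm M YKL-5-124 replicate 2. Between times in arm M they were CCL8 (-5.55), MT1M (-5.51) and CCL2 (-5.10) below, and MNDA (2.62), LRG1 (1.80) and MGST1 (1.75) above. In arm P they were CCL7 (-7.35), CCL8 (-6.59) and CCL13 (-6.51) below, and PID1 (2.74), RMRP (2.34) and ATP6V1C2 (2.32) above. LRG1 lost its call without 8 of the 12 libraries (adjusted p 0.051 to 0.074), the exceptions being 6 h DMSO replicates 2 and 3, 6 h YKL-5-124 replicate 1 and 24 h YKL-5-124 replicate 2. MGST1 lost it without 8 of 12 (adjusted p 0.052 to 0.11), the exceptions being 6 h DMSO replicate 2, 6 h YKL-5-124 replicate 3, 24 h DMSO replicate 3 and 24 h YKL-5-124 replicate 1. RMRP lost it without 9 of 12 (adjusted p 0.052 to 0.11), the exceptions being 6 h DMSO replicate 3, 24 h DMSO replicate 3 and 24 h YKL-5-124 replicate 2.

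Lists whose difference camera called also with an estimated correlation were the E2F and DNA replication list (median -1.32 at 6 h and -2.58 at 24 h between arms), the G2 and mitosis list (-0.83 and -1.39), the erythroid markers (1.77 between arms at 24 h and 1.23 between times in arm P) and the monocyte markers (-2.40 between times in arm P). After centring the calls of the erythroid markers ended (adjusted p = 0.065 and 0.074). Only 1 member of the G2 and mitosis list reached 5 FPKM in arm M DMSO, so its difference cannot be separated from the low level there.

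Other splits of the libraries, with main effects removed, were compared with these counts. Between arms the real split gave 160 calls at 6 h, more than any of the other splits (highest 3; 1 of 100 as large), and 763 at 24 h (highest other 56; 1 of 100). Between times in arm M it gave 355 (highest other 13; 1 of 100). In arm P it gave 2095, and 3 of 100 splits were as large, the highest with 3810. Library structure or a random division is thus not excluded there on the deposited scale. On centred values the real split gave 2332 and the highest other 8. The other shares leave little room for a random division.

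For comparisons of 3 against 3 libraries the 10 splits are too few to exclude chance, and in each the real split was the 1 with the most calls. The drug effect gave 5530 calls (highest other split 2) in arm M at 6 h, 7566 (6) at 24 h, 3191 (2) in arm P at 6 h and 8300 (1) at 24 h. The arms gave 5418 (1) in DMSO at 24 h, 5436 (1) and 3269 (3) in YKL-5-124 at 6 and 24 h, and 5363 in DMSO at 6 h, where another split gave 3448, a structure of library levels that centring removed (7319, highest other 0, limma). Times in DMSO gave 3257 (2) in arm M and 249 (5) in arm P.

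The first pattern weighed is the lower level over all genes with YKL-5-124. Scale differences of single libraries would spread over both treatments, but a two-sided exact permutation within the 4 strata of arm and time gave p = 2.5e-05 over 160000 divisions (mean shift of library medians -0.69), while each stratum alone reaches no p below 0.1. Fewer cells or less recovered RNA in treated wells cannot be told apart from less RNA per cell, since the ratio of totals was as low as 0.43 and no cell count per library is given. The design text speaks of normalization to cell number, which, if done for each well, goes against fewer cells but not against less recovered RNA. No biological explanation was tested.

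The second pattern is the larger fall of the E2F list in arm P at 24 h. Differences in library scale do not account for it, since its median was -2.50 on centred values (adjusted p = 3.8e-05 with an estimated correlation). Low starting levels in arm M are not the whole cause, since the 11 members with at least 5 FPKM in arm M DMSO had a median of -1.95, 10 of them called lower. Loss of all T cells alike in arm P would lower their markers as much. Their median difference was -0.06 ± 0.15 (21 markers, 1 called lower). These values argue against all 3 as the whole cause. No other cause, such as T cell subset loss, was tested.

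The third pattern is the fall of monocyte markers at 24 h. A loss of monocytes as the whole cause would lower all their abundant markers, and in arm M 3 of 18 markers with at least 10 FPKM in DMSO were not called lower (CD14, S100A8 and VCAN, the highest VCAN at 0.36). In arm P all 15 such markers fell, the least CD68 (-2.10), so a loss of monocytes and lower expression in them cannot be told apart there from transcript levels. The difference between arms in this list was not called with an estimated correlation (median -1.12, adjusted p = 0.71; 0.017 after centring).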

How the results depend on the processing

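The spike-in component, alone or with centring, and centring with the estimated correlation were tests chosen after the data were seen; the other alternatives were planned. Counts of called genes are given where they moved by over 1.5 times. Drug by arm and drug by time are the differences of the drug effect between arms and times.

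The 408 values for 205 named genes were recomputed 7022 times, and 6713 of these values had the same direction and side of the threshold. No named gene changed sign with a call on either side except under centring, alone or with the spike-in component, or quantile normalization. Of 394 called values the call ended for 37 after median centring, 39 after quantile normalization and 38 after centring with the spike-in component. It ended for 8 without a filter, 14 with own groups only, 6 at a pseudocount of 0.1, 7 with spike-in rescaling, 5 with the spike-in component, 3 with the replicate block and 1 without the trend. With the stricter filter it ended for 1 of 337, and with a library left out for 98 of 2508.

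Median centring removes the level over all genes, and so it changed which genes stood above 0. The count became 3220 for the drug in arm M at 6 h and 5329 for the arms in YKL-5-124 at 24 h. It was 827 for drug by arm at 6 h and 2212 at 24 h. It was 816 for drug by time in arm M and 256 for time in arm M. It was 26 for time in arm P. Signs reversed, with a call on either side, as CENPE 0.09, RPL15 0.01 and GP1BA 0.08 for the drug in arm M at 6 h. Others were GP1BA 0.00, CDK7 0.61, E2F1 0.07 and HEXIM1 0.75 for the drug in arm M at 24 h. Others were HEXIM1 0.41 for the drug in arm P at 6 h. Others were CDK7 0.01 for the drug in arm P at 24 h. The ribosomal protein list for time in arm M went from 0.39 to -0.16. With centring and the spike-in component the count became 5372 for the arms in YKL-5-124 at 24 h and 831 for drug by arm at 6 h. It was 2358 for drug by arm at 24 h and 981 for drug by time in arm M. It was 352 for time in arm M and 33 in arm P. Signs reversed as CENPE 0.08, RPL15 0.00 and GP1BA 0.08 for the drug in arm M at 6 h. Others were CDK12 0.04, GP1BA 0.16, HBA1 0.35, CDK7 0.66, E2F1 0.22 and HEXIM1 0.78 for the drug in arm M at 24 h. Others were ENO1 0.03, NDUFA9 0.05, RPS16 0.11, JCHAIN 0.00 and HEXIM1 0.44 for the drug in arm P at 6 h. Others were CDK7 0.01 for the drug in arm P at 24 h. Quantile normalization also removes the level. The count became 4956 for the drug in arm M at 24 h and 4441 for the drug in arm P at 24 h. It was 5769 for the arms in YKL-5-124 at 24 h and 876 for drug by arm at 6 h. It was 1957 for drug by arm at 24 h and 1253 for drug by time in arm M. It was 50 for time in arm M and 7 in arm P. Signs reversed as ENO1 0.00 and MCL1 0.13 for the drug in arm M at 6 h. Others were CDK7 0.67 and HEXIM1 0.92 for the drug in arm M at 24 h. Others were HEXIM1 0.34 for the drug in arm P at 6 h. Others were MCL1 0.30 and CDK7 0.16 for the drug in arm P at 24 h. Others were MCL1 -0.46 for the arms in DMSO at 6 h. Others were XBP1 0.00 and MCL1 -0.59 for the arms in DMSO at 24 h.

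A minimum absolute log2 fold change of 1 lowers the count by construction. It was 2017 for the drug in arm M at 6 h and 3625 at 24 h. It was 1326 for the drug in arm P at 6 h and 4930 at 24 h. It was 2967 for the arms in DMSO at 6 h and 3023 at 24 h. It was 3244 for the arms in YKL-5-124 at 6 h and 1714 at 24 h. It was 399 for time in arm M and 79 in arm P. Fitting own groups only uses fewer libraries for the variance, and gave 3200 for the drug in arm M at 6 h and 3457 for the arms in DMSO at 6 h. It was 97 for drug by arm at 6 h and 1135 for drug by time in arm P. It was 8 for time in arm M and 11 in arm P. The stricter filter tests fewer genes, and gave 83 for drug by arm at 6 h and 442 at 24 h. It was 1365 for time in arm P. Without a filter the count was 1876 for time in arm M, and without the trend 134 for time in arm P. With a pseudocount of 0.1 it was 66 for drug by arm at 6 h and 117 for time in arm P. With spike-in rescaling it was 1 for time in arm P. With the spike-in component it was 6042 for the drug in arm P at 6 h and 1156 for drug by arm at 24 h. It was 1183 for drug by time in arm M and 5058 for time in arm M. The cause was not tested. Replicate numbers did not pair libraries (correlations of same-numbered libraries -0.25 to 0.22), and with the replicate block the count was 2016 for time in arm M and 7 in arm P.

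With the estimated correlation, the 10, 14, 10 and 17 lists called for the drug in arm M at 6 and 24 h and in arm P at 6 and 24 h became 0, 0, 0 and 1, with 0, 2, 2 and 5 at an unadjusted p under 0.05 in camera and 22, 24, 12 and 25 called by fry. In the order of the arms in DMSO (6, 24 h), the arms in YKL-5-124 (6, 24 h), drug by arm (6, 24 h), drug by time (arms M, P) and time (arms M, P), the numbers went from 17, 18, 16, 15, 9, 10, 10, 14, 14 and 11 to 1, 0, 0, 2, 2, 3, 0, 2, 0 and 0; unadjusted, 4, 6, 4, 4, 2, 3, 5, 3, 1 and 1, and by fry 21, 22, 20, 16, 3, 4, 9, 16, 20 and 14. With centring as well they were 1, 5, 2 and 6 for the drug and 6, 7, 6, 4, 2, 3, 4, 4, 0 and 0 for the others (for time, 4 and 1 at an unadjusted p under 0.05). The lists for time in arm P numbered 5 with centring and 5 at a pseudocount of 0.1.

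Leaving out a library uses fewer samples, and counts ran over 2629 to 6943 for the drug in arm M at 6 h and 5745 to 7544 at 24 h. They ran over 1716 to 4539 for the drug in arm P at 6 h and 6619 to 8916 at 24 h. They ran over 4377 to 5537 for the arms in DMSO at 6 h and 4434 to 5291 at 24 h. They ran over 4459 to 5072 for the arms in YKL-5-124 at 6 h and 2478 to 3146 at 24 h. They ran over 93 to 277 for drug by arm at 6 h and 580 to 934 at 24 h. They ran over 249 to 506 for drug by time in arm M and 950 to 3583 in arm P. They ran over 43 to 6715 for time in arm M and 0 to 4673 in arm P. The level over all genes ran over -0.67 to -0.37 for the drug in arm M at 6 h and -0.73 to -0.55 at 24 h. It ran over -0.45 to -0.19 for the drug in arm P at 6 h and -0.92 to -0.62 at 24 h. It ran over -0.01 to 0.29 for the arms in DMSO at 6 h and 0.03 to 0.26 at 24 h. The level stayed below 0 in all 4 drug comparisons, and for the arms in DMSO at 6 h it turned to -0.01 without arm M DMSO replicate 3. For the drug in arm M at 6 h the count moved to 2629 without DMSO replicate 1 and 3236 without YKL-5-124 replicate 3, and in arm P at 6 h to 1839 without DMSO replicate 2, 1716 without DMSO replicate 3 and 1990 without YKL-5-124 replicate 3. For time in arm M it moved to 6715 without 6 h DMSO replicate 1, 606 without 6 h DMSO replicate 2, 43 without 6 h DMSO replicate 3, 986 without 24 h DMSO replicate 1, 87 without 24 h DMSO replicate 2 and 57 without 24 h DMSO replicate 3, and in arm P to 4 without 6 h DMSO replicate 1, 1196 without 6 h DMSO replicate 2, 1234 without 6 h DMSO replicate 3, 0 without 24 h DMSO replicate 1, 4673 without 24 h DMSO replicate 2 and 0 without 24 h DMSO replicate 3 (2521 and 2440 genes at an unadjusted limma p under 0.05 for the counts of 0). Depth is unknown, so how it limits low genes was not examined.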

Other observations

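The gene families here were chosen after the results were seen. In parentheses the last 2 numbers are camera adjusted p with an estimated correlation, on the deposited scale and after centring. Metallothionein genes, which bind zinc and copper, were higher in arm P than in arm M in DMSO, 13 of 14 at 6 h (median 4.07, centred 3.92, 0.063 and 0.041) and 12 of 14 at 24 h (median 3.64, centred 3.56, 0.1 and 0.069). With YKL-5-124 at 24 h 9 of 14 were lower in arm M (median -2.78, centred -1.97, 0.51 and 0.13) and 13 of 14 in arm P (median -3.32, centred -2.42, 0.35 and 0.1). These paralogs share reads, so members are not independent.

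Proteasome subunit genes and mitochondrial ribosomal protein genes were higher in arm P in DMSO at 6 h, 37 of 43 (median 1.52, centred 1.37, 0.18 and 0.03) and 72 of 80 (median 1.35, centred 1.20, 0.18 and 0.0077). With an estimated correlation camera called both only after centring. HLA genes, which present antigen, were lower with YKL-5-124 at 24 h in both arms, 19 of 22 in arm M (12 after centring; median -1.60, centred -0.79, 0.48 and 0.013) and 15 of 22 in arm P (10 lower and 3 higher after centring; median -1.21, centred -0.31, 0.64 and 0.2). In arm P camera did not call them at the preset correlation (adjusted p = 0.14). Markers of B cells, monocytes and dendritic cells fell in both arms too. At 6 h 11 HLA genes were lower in arm M (median -0.83, centred -0.20, 0.61 and 0.42), while in arm P 1 was higher and 2 lower, against 14 higher after centring (median 0.31, centred 0.73, 0.73 and 0.26). The drug effect on HLA genes differed between arms by 1 called gene at 6 h and 10 after centring (median 1.01, centred 0.80, 0.25 and 0.011), and by 4 at 24 h and 7 after centring (median 0.56, centred 0.64, 0.55 and 0.048).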
